A study of Homo sapiens with 4 samples.

How the data were processed

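Gene expression was measured in 4 samples of human tumours grown in nude mice, 2 from control cells and 2 from TSPAN12 knockdown cells, each on 1 single-colour array. Per the labels' protocols, tumours grew in the mammary fat pads for 34 days and a piece of each was used to prepare total RNA. Complementary RNA was made from an oligo-dT primer carrying a T7 promoter and labelled with biotin, so the signal favours the 3′ end of transcripts. The labels do not name the cell line, the sequences used for the knockdown or the control, and the genome build behind the probe annotation is not given in the sources used here.

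The deposited values were intensities on a linear scale, 1 per probe set and array, and per the submitters' processing notes they were made with RMA, whose version is not given in the sources used here. RMA adjusts the background, equalises the distributions of the arrays and summarises the probes of a set, so differences in total RNA between samples are not retained and small values are compressed. The deposited table with gene descriptions and the deposited series table held the same 22277 probe sets, and their intensities differed by at most 5e-10 of their value. The first was used, and the second therefore moved no result. The lowest intensity was 6.13 and the highest 24081, and medians lay at 98.4, 98.5, 101 and 99.2. No detection calls were used, so the depth of a value is given as its intensity.

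Of the 22277 probe sets, 62 were array controls, 1258 had no gene symbol, 583 had several and 20374 had 1. The 12754 symbols of the last kind were brought up to date with the RefSeq gene table of GRCh38.p14, used for names only: 11452 were current, 1084 were replaced through a listed synonym and 218 were kept as given. This left 12748 genes. For a gene with several probe sets, the brightest on average over all arrays was used. Among the genes that passed, 394 had more than 1 probe set and for 83 of these another probe set had the opposite sign. Signal from related genes can enter probe sets with the suffix _x_at, which read 57 of the genes that passed.

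Intensities were put on the log2 scale after setting values under 1 to 1. Genes in the lowest 25 percent by mean log2 value, at a linear level of 34.3 or less, were left out, 3187 in all, and 9561 were tested. Knockdown was compared with control in R 4.3.3 with limma 3.58.1, using lmFit and eBayes without an intensity trend, two-sided, with a Benjamini-Hochberg threshold of 0.05. The fit had 2 residual degrees of freedom, 3.33 prior degrees of freedom and a median residual SD of 0.0821 on the log2 scale. Where a group's mean of a named gene lay below 34.3, values under that level were set to it for the fold, which is given as a bound and was chosen after the values were seen, while log2 differences are as measured. Errors given as ± are standard errors of this fit unless named as SD. Log2 differences are knockdown minus control.

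Before the data were examined, 37 gene lists, the test, the alternatives and the rule for naming genes were fixed. The lists covered Wnt receptors and pathway components, β-catenin targets, tetraspanins, 25 lists of cell processes and 9 lists of markers of other cell types. Lists with at least 5 tested genes, 35 in all, were tested as sets with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Counts of members are given over all tested genes and adjusted over the list alone. The rule named TSPAN12, the 15 genes per direction with the largest differences among those that passed with groups that did not overlap, and up to 4 members of each list. CTNNB1, FZD4, TCF7L2, LEF1 as a pathway component, CCND1, MYC, VEGFA, THBS1, ID4, SFN, KRT17, ITGB5, EFNB2, FGF5, SEMA3F and COL3A1 fell outside it and were chosen after their values were seen. A few genes that the rule selects are not reported here.

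The alternatives were no filter, a filter on the lower-expressed 50 percent, eBayes with an intensity trend, the mean of a gene's probe sets, the other deposited table, quantile normalization, centring each array on its median, the replicate number as a block, each array left out in turn, a threshold of 0.1, a threshold of 0.05 with at least 2-fold, probe sets tested one by one, camera with an estimated correlation, and fry. The replicate numbers do not pair the samples, since the labels give no shared animal, litter or day.

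The procedure was tested on simulated arrays of the same 9561 genes, 2 against 2, with 200 genes changed. It recovered 26.9% of genes changed by 0.5 on the log2 scale, 92.5% of those changed by 1 and 100% of those changed by 2. Of 149 calls, 3 were wrong, and with no gene changed 0 were made. With 2000 genes all changed by 0.5, 82.2% were recovered and 3.58% of calls were wrong. The simulated genes were independent, and their variances were drawn from the prior of the fit, so the assumptions of the test held. Few wrong calls were thus built in, and these shares do not measure the errors among the calls in the tumours. A list of independent genes shifted by -0.46 gave a camera adjusted p of 2.45e-50, an adjusted p of 0.109 with an estimated correlation and a fry adjusted p of 0.0231, and 0 other lists were called. With 2 residual degrees of freedom, the correlation between genes of a list is estimated poorly.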

Results

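Gene expression was measured on oligonucleotide microarrays in pieces of 4 xenograft tumours, 2 from control cells and 2 from cells in which TSPAN12 had been knocked down. TSPAN12 is a tetraspanin, a membrane protein known as a co-receptor of the Norrin and Frizzled-4 branch of β-catenin signalling. The tumours were removed from the mammary fat pads of nude mice on day 34. The deposited table held 1 intensity for each of 22277 probe sets on each array, and 9561 genes entered the test. Median intensities were 98.4 and 98.5 on the control arrays and 101 and 99.2 on the knockdown arrays. Across probe sets, which are not independent replicates, log2 values correlated at r = 0.997 between the controls, 0.996 between the knockdown arrays and 0.986 to 0.989 between the groups. The labels number the samples but do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision, since the smallest two-sided exact permutation p for 2 against 2 arrays is 0.333. Probe sets for 18S ribosomal RNA read 10771 and 9182 on the control arrays and 6212 and 3848 on the knockdown arrays, 1.98-fold lower in the knockdown group. The ratio of 3′ to 5′ signal of ACTB was 1.68 and 1.77 in the controls and 1.53 and 2.32 in the knockdown samples.

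The first question was whether the targeted transcript was lower in the samples labelled as knockdown. TSPAN12, read by a single probe set, had an intensity of 199 and 201 in the controls and of 35.9 and 34.4 in the knockdown tumours. It fell by 2.51 ± 0.07 on the log2 scale (SE of the limma fit, n = 2 per group, adjusted p = 0.000876), or 5.70-fold. Its rank on the array dropped from the 61.3 and 61.6 percentiles to the 32.2 and 31.0 percentiles. TSPAN12 stood 9th among all tested genes by the size of its measured difference and 2nd among the lower ones.

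The design compares knockdown with control tumours, and the main question was which other transcripts differed with TSPAN12. Where a group's mean lay below 34.3, the level under which genes were left out, the fold was taken against that level as a bound. The proprotein convertase gene PCSK5 rose at least 10-fold (measured difference 3.77 ± 0.19 on the log2 scale, adjusted p = 0.00329), from a mean intensity of 25.2 in the controls. The cancer-testis antigen gene MAGEB2 rose at least 5.70-fold (3.22 ± 0.14) from 21 and SLC2A10, which encodes the glucose transporter GLUT10, at least 4.44-fold (2.78 ± 0.08) from 22.2. CST7, which encodes the cysteine protease inhibitor cystatin F, rose 8.42-fold (3.07 ± 0.10). The smooth muscle actin gene ACTG2 rose 6.58-fold and TAGLN, an actin-binding protein of smooth muscle, 5.98-fold. Secreted or secretory-pathway products were INHBB, the activin βB subunit (5.45-fold), the proteoglycan SPOCK1 (7.49-fold), the carboxypeptidase CPE (3.48-fold), the complement C1 inhibitor SERPING1 (3.20-fold) and KISS1, the precursor of kisspeptin (3.52-fold). Receptors and adhesion molecules were L1CAM (4.31-fold), the netrin receptor NEO1 (3.22-fold) and the collagen-binding integrin subunit ITGA10 (3.18-fold). NNMT, a methyltransferase of nicotinamide, rose 5.17-fold. The limma adjusted p of these 15 genes lay at 0.000876 for the lowest and 0.0315 for KISS1, the highest. The SPOCK1 controls differed widely, with intensities of 413 and 148, and a second L1CAM probe set at an intensity of 56.9 gave a log2 difference of -0.03.

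Among the lower genes, MX1, an interferon-induced antiviral GTPase, fell by 2.72 ± 0.10 on the log2 scale, 6.59-fold (limma adjusted p = 0.00144). BCL2A1, a BCL2 family member that restrains apoptosis, fell 3.74-fold. The cyclin gene CCNA1 fell 3.55-fold, the extracellular glutathione peroxidase GPX3 3.05-fold and the zinc finger gene ZNF804A 2.93-fold. CCL2, a chemokine that attracts monocytes, fell 2.80-fold and S100A4, a calcium-binding protein linked to cell motility, 2.76-fold. Genes of cell adhesion and the cytoskeleton were MPZL2 (2.76-fold lower), HCLS1 (at least 1.90-fold lower) and the tight junction gene CLDN4 (2.40-fold lower). The cancer-testis genes SPANXC (4.42-fold) and MAGEC2 (2.43-fold) were also lower, whereas MAGEB2 was higher. SPANXC and the pseudogene MEIS3P1 (at least 2.25-fold lower) were read by probe sets that share probes with related sequences, so the source of their signal is uncertain. A dim second probe set of MAGEC2, at an intensity of 15.7, gave a log2 difference of 0.14.

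Of the 9561 genes tested with limma, 1002 passed a Benjamini-Hochberg threshold of 0.05, which is 10.5%. Of these, 460 were higher and 542 lower in the knockdown tumours. Most differences were small, with a median of 1.45-fold for the higher and 1.43-fold for the lower genes, and 54 higher and 33 lower genes changed at least 2-fold. Both knockdown arrays lay on one side of both controls for 5781 genes, or 60.5%, where chance gives 33.3% on average over the possible splits into pairs. Genes are not independent of one another, so the share describes these 4 arrays and is no test of the knockdown. With 3 arrays, a single residual degree of freedom is left, and 51 genes passed without control replicate 1, 31 without control replicate 2, 48 without knockdown replicate 1 and 41 without knockdown replicate 2. Of the 30 genes chosen for size, 14 passed with every array left out in turn. These were PCSK5, MAGEB2, CST7, SLC2A10, INHBB, CPE and ITGA10 among the higher genes, and MX1, TSPAN12, SPANXC, BCL2A1, GPX3, ZNF804A and CCL2 among the lower ones. L1CAM and MAGEC2 passed in none of the 4 fits with an array left out.

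**Figure D1:**
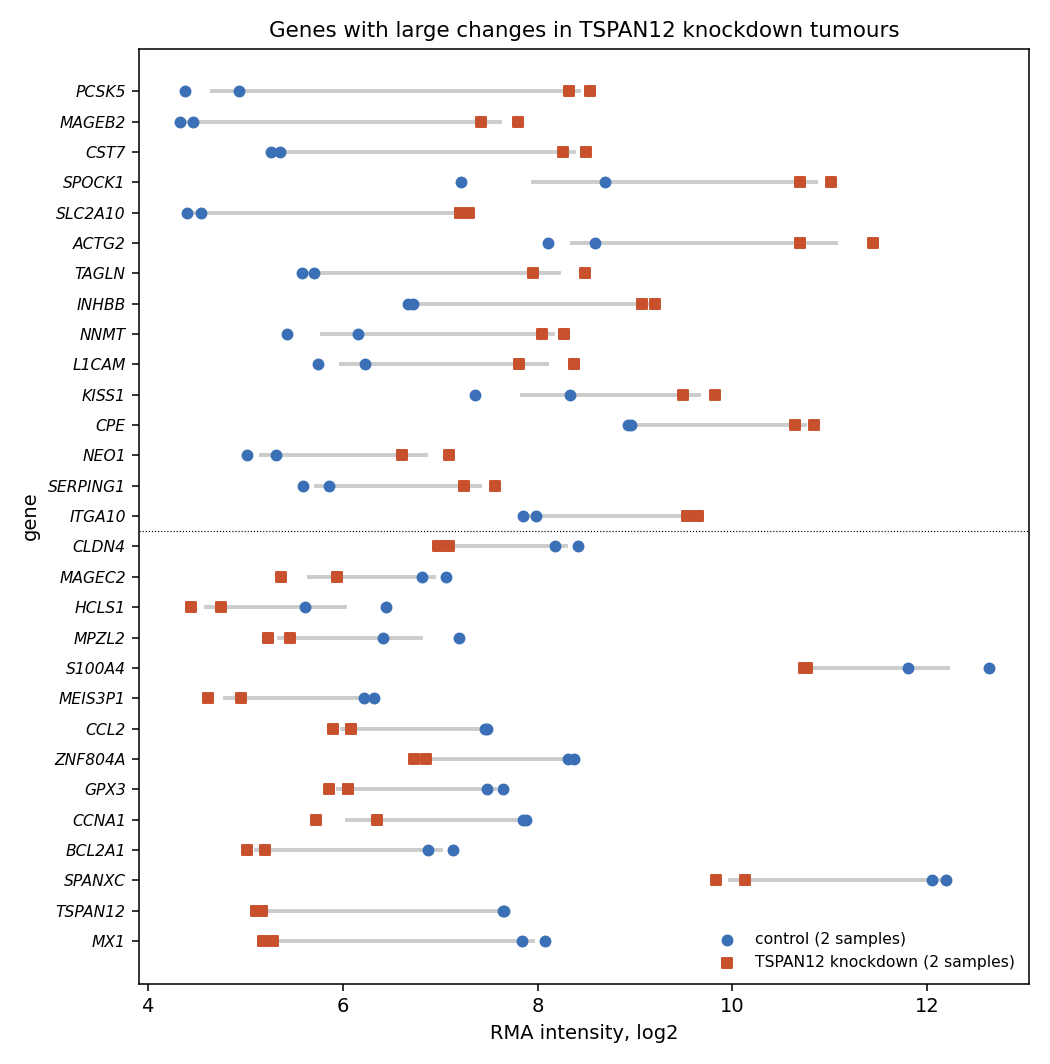
Log2 intensity per array of TSPAN12 and of the other genes reported for the size of their difference, with control samples as blue circles, knockdown samples as orange squares and a grey line joining the 2 group means of each gene. TSPAN12 moved from a log2 mean of 7.65 to 5.14, and PCSK5 from 4.66 to 8.43.

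A link between TSPAN12 and β-catenin is named in the title of the series, so Wnt receptors, pathway components and target genes were examined as lists. The transcript level of CTNNB1, which encodes β-catenin, differed by 0.09 ± 0.07 on the log2 scale (limma adjusted p = 0.424). The arrays do not measure the level or activity of β-catenin protein. Of 40 tested Wnt receptors and pathway components, 5 rose, 1 fell and 34 did not pass. Adjusted over the list alone, 8 rose and 3 fell. The gene that fell was the receptor FZD3 (-0.98 ± 0.14). The genes that rose were the co-receptor LRP5 (0.43), the Wnt secretion factor WLS (0.43), the β-catenin inhibitor CTNNBIP1 (0.36) and the transcription factors TCF7L2 (0.33) and LEF1 (0.33). The list did not pass as a set (median 0.11, camera adjusted p = 0.0837), but it did when the lower-expressed 50% of genes were left out (median 0.12, adjusted p = 0.0392). FZD4, the receptor with which TSPAN12 acts, differed by 0.36 ± 0.12 (adjusted p = 0.112). Without any single array, none of these members passed.

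Among 26 tested β-catenin target genes, 3 rose and 1 fell, and adjusted over the list alone 4 rose and 5 fell. L1CAM (2.11), TNFRSF11B, which encodes osteoprotegerin (0.86), and LEF1 rose, and CCN4 fell (-0.73). The CCN4 mean in the knockdown tumours, 33.2, lay below the filter level of 34.3, so its fold is at least 1.55. The widely used targets CCND1 (0.09 ± 0.09, limma adjusted p = 0.522) and MYC (-0.16 ± 0.08, adjusted p = 0.271) did not pass. The list median was 0.02 and the camera adjusted p was 0.79. Dimmer probe sets of LEF1 and CCN4 gave log2 differences of -0.02 and 0.06, opposite in sign to those tested. In the tetraspanin family of 19 tested genes, TSPAN31 rose (0.46 ± 0.09), and TSPAN13 fell (-0.95 ± 0.07, adjusted p = 0.00864) along with TSPAN12. Adjusted over the list alone, 2 tetraspanins rose and 2 fell, and the camera adjusted p was 0.947. CD82 differed by 0.41 ± 0.09 (adjusted p = 0.0508). With each array left out in turn, TSPAN12 itself stayed lower in all 4 fits, by -2.54 to -2.48. TSPAN13, TSPAN31, L1CAM, TNFRSF11B, LEF1 and CCN4 passed in none of these fits.

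Genes of mitosis were lower in the knockdown tumours as a group. Of 38 tested G2/M and mitosis genes, 22 fell and none rose, all 38 differences were negative, and 37 had both knockdown arrays below both controls. The kinetochore gene NDC80 fell 1.96-fold (-0.97 ± 0.11), the spindle gene DLGAP5 1.79-fold (-0.84 ± 0.10), cyclin B1 (CCNB1) 1.64-fold (-0.71 ± 0.08) and the spindle checkpoint kinase BUB1 1.57-fold (-0.65 ± 0.09). Of 35 tested genes of G1/S and DNA replication, 10 fell, among them cyclin E2 (CCNE2, -0.80 ± 0.09), thymidylate synthase (TYMS, -0.73 ± 0.08), MCM10 (-0.73 ± 0.11) and RFC5 (-0.67 ± 0.11), and none rose. Adjusted over the list alone, 35 mitosis genes and 13 replication genes fell. The medians were -0.46 (camera adjusted p = 1.98e-16) and -0.22 (camera adjusted p = 8.09e-08). Both calls were lost with an estimated correlation, with adjusted p = 0.802 with an estimated correlation for each list. In fits without control replicate 1, 1 mitosis gene passed, in those without any other single array 0 passed, and no replication gene passed in any of the 4. The 18S ribosomal RNA signal, 1.98-fold lower in the knockdown group, moved with these lists. Of the other probe sets of BUB1, a pair of dim ones gave 0.09 and 0.14.

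Hypoxia response genes were higher in the knockdown tumours. Of 26 tested members, 12 rose and none fell, 16 rose when adjusted over the list alone, and 17 had both knockdown arrays above both controls. The vasoactive peptide gene ADM rose 2.60-fold (1.38 ± 0.25, limma adjusted p = 0.0318), TMEM45A 1.98-fold (0.98 ± 0.09), the lipase inhibitor ANGPTL4 1.81-fold (0.85 ± 0.11) and the MYC antagonist MXI1 1.79-fold (0.84 ± 0.10). VEGFA, the main angiogenic factor of the list, differed by 0.34 ± 0.19 (adjusted p = 0.278). The list median was 0.48 (camera adjusted p = 3.27e-06, and adjusted p = 0.802 with an estimated correlation). Leaving out knockdown replicate 1 left 1 member past the threshold, and leaving out any of the other 3 arrays left 0. Glycolysis enzymes did not pass as a set: of 18 tested, the neuronal enolase gene ENO2 rose (0.90 ± 0.09, adjusted p = 0.0147), alone also when adjusted over the list alone, and the camera adjusted p was 0.623. The lower 18S ribosomal RNA signal of the knockdown arrays accompanied the hypoxia genes too.

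TGF-β response genes were also higher, with 7 of 26 tested members rising and 2 falling (9 and 2 when adjusted over the list alone). TAGLN rose most, followed by the transcriptional inhibitor ID3 (1.13 ± 0.09, 2.20-fold, limma adjusted p = 0.012), the inhibitory SMAD gene SMAD6 (0.89 ± 0.10) and ANGPTL4, which the hypoxia list also holds. THBS1 (-0.61 ± 0.10) and ID4 (-0.71 ± 0.10) fell. Dimmer probe sets of SMAD6 gave -0.04, 0.14 and 0.44. The list median was 0.31 (camera adjusted p = 0.000879, and adjusted p = 0.802 with an estimated correlation), and with 1 array left out it lay between 0.20 without control replicate 2 (adjusted p = 0.00179) and 0.42 without control replicate 1 (adjusted p = 1.64e-05). When control replicate 1, control replicate 2, knockdown replicate 1 or knockdown replicate 2 was left out, 2, 0, 1 and 2 members passed as higher. The camera call ended when the lower-expressed 50% of genes were left out (median 0.18, adjusted p = 0.0516). Among 15 tested heat shock genes, the co-chaperone DNAJB4 fell 2.19-fold (-1.13 ± 0.08, adjusted p = 0.00864) and 14 did not pass, with 3 lower when adjusted over the list alone. The heat shock list had a median of -0.20 (camera adjusted p = 0.022, and adjusted p = 0.883 with an estimated correlation). That call was lost without control replicate 1 (-0.11, adjusted p = 0.169) and without knockdown replicate 1 (-0.14, adjusted p = 0.0934). As for the lists above, the 18S ribosomal RNA signal, 1.98-fold lower in the knockdown group, moved with the TGF-β and heat shock lists.

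**Figure D2:**
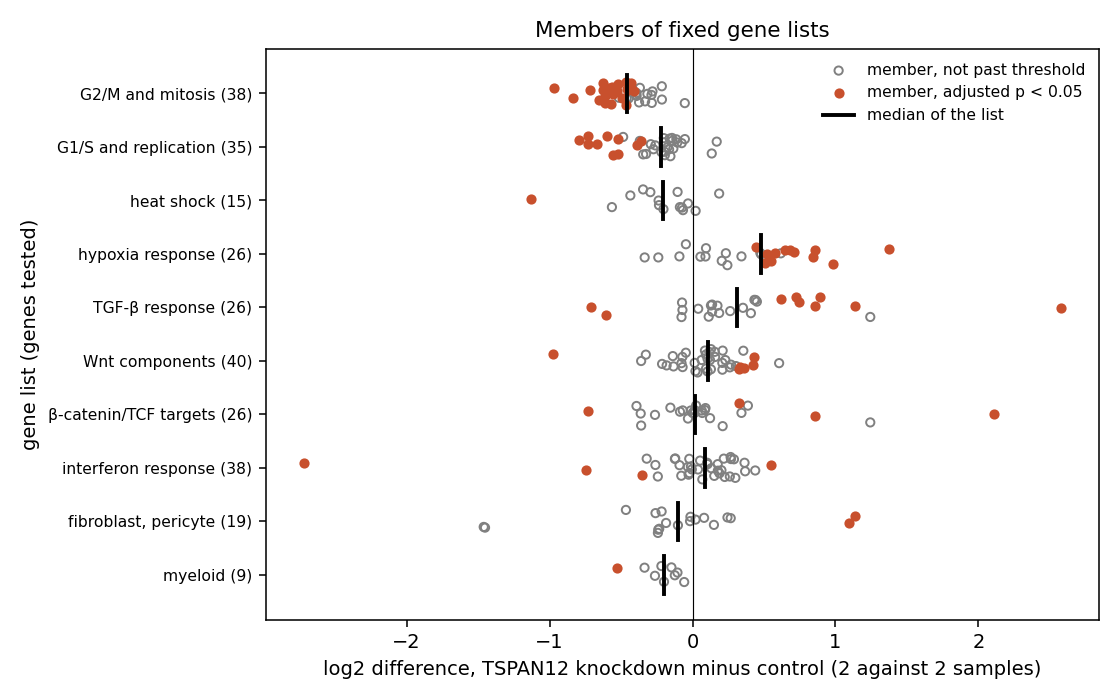
Log2 differences, knockdown minus control, of the tested members of gene lists, with a point per gene, filled where its adjusted p passed 0.05, scattered vertically for legibility, and a black bar at the median of each list. The mitosis list lies at a median of -0.46 with all 38 members below 0, and the hypoxia list at a median of 0.48.

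Genes of epithelial junctions and of the extracellular matrix went both ways. Among 20 tested epithelial genes, the claudins CLDN4 and CLDN7 (-0.76 ± 0.07), the keratin KRT19 (-1.22 ± 0.10) and SFN (-0.62 ± 0.08) fell, and the keratins KRT81 (0.65 ± 0.13) and KRT17 (0.33 ± 0.07) rose. Adjusted over the list alone, 4 rose and 5 fell, and the camera adjusted p was 0.124, and 0.0136 when the lower-expressed 50% of genes were left out. Of 18 tested mesenchymal genes, the gelatinase gene MMP2 rose (0.80 ± 0.14) and S100A4 fell, 1 each also when adjusted over the list alone (camera adjusted p = 0.798). MMP2 was the only 1 of 29 extracellular protease and inhibitor genes to pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.353). Of 19 tested integrin and laminin genes, ITGA10, LAMC1 (0.59 ± 0.08), LAMB2 (0.49 ± 0.08) and ITGB5 (0.48 ± 0.07) rose and LAMB3 (-0.52 ± 0.07) fell, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.292). Of 24 secreted angiogenesis regulators, the growth factor genes PDGFB (0.99 ± 0.11) and FGF1 (0.78 ± 0.10) rose with ANGPTL4 and EFNB2 (0.48 ± 0.09). SEMA3A (-0.63 ± 0.08), FGF5 (-0.48 ± 0.08), SEMA3F (-0.45 ± 0.09) and THBS1 fell, with the same counts of 4 and 4 adjusted over the list alone (camera adjusted p = 0.623). A pair of dim PDGFB probe sets gave -0.17 and -0.15, and another, at an intensity of 64.6, gave 0.69. In fits without control replicate 1, control replicate 2, knockdown replicate 1 or knockdown replicate 2, 1 epithelial gene was lower and 1 integrin or laminin gene higher each time. Of the other lists here, 1 mesenchymal gene was lower and 1 angiogenesis regulator higher without control replicate 1, and 0 passed otherwise.

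In the interferon list of 38 tested genes, MX1, IFI44 (-0.74 ± 0.10) and GBP1 (-0.35 ± 0.07) fell and MX2 (0.55 ± 0.08) rose, with 2 higher and 3 lower adjusted over the list alone. A dim IFI44 probe set, at an intensity of 16.4, gave 0.32. The interferon median was 0.09, the mean -0.01 and the camera adjusted p 0.605. Among 23 NF-κB and inflammatory cytokine genes, CCL2 fell and the neutrophil chemokine CXCL1 rose (0.63 ± 0.11), 1 each also when adjusted over the list alone (camera adjusted p = 0.947). Of 20 tested NRF2 target genes, the glutathione synthesis gene GCLM (-0.84 ± 0.11), TALDO1 (-0.58 ± 0.07) and ME1 (-0.55 ± 0.08) fell, with 2 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.81). The ME1 direction depends on the probe set, since another at an intensity of 316 gave 1.75. Of 21 p53 target genes, GADD45A (0.65 ± 0.13) and PLK3 (0.51 ± 0.08) rose and TP53I3 (-0.40 ± 0.08) and PPM1D (-0.33 ± 0.07) fell, with 2 and 5 adjusted over the list alone (camera adjusted p = 0.524). Of 25 apoptosis-promoting genes, FADD (-0.44 ± 0.07) and CYCS (-0.38 ± 0.08) fell, 5 when adjusted over the list alone (camera adjusted p = 0.137). Of 15 apoptosis-restraining genes, BCL2A1 and FAIM (-0.50 ± 0.07) fell, 3 when adjusted over the list alone (camera adjusted p = 0.798). Without each single array in turn, MX1, CCL2 and BCL2A1 passed every time, and no other member of these lists passed.

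The remaining lists of cell processes held few changes. In the unfolded protein response list of 22 genes, PPP1R15A rose (0.50 ± 0.09) and SDF2L1 fell (-0.34 ± 0.07), with 5 and 2 adjusted over the list alone (camera adjusted p = 0.137, and 0.0277 without control replicate 1). Among 27 immediate early genes, KLF4 rose (0.40 ± 0.07) and PHLDA1 fell (-0.54 ± 0.08), 1 each also adjusted over the list alone (camera adjusted p = 0.218). Of 22 cholesterol synthesis genes, the squalene synthase gene FDFT1 fell (-0.53 ± 0.08), alone also when adjusted over the list alone (camera adjusted p = 0.218). Of 18 YAP/TEAD targets, IGFBP3 rose (0.78 ± 0.15) and DLC1 (-0.61 ± 0.10) and FOXF2 (-0.40 ± 0.07) fell, with 3 and 3 adjusted over the list alone (camera adjusted p = 0.947). Of 15 Notch pathway genes, NOTCH4 fell (-0.35 ± 0.07), and 0 passed when adjusted over the list alone (camera adjusted p = 0.46). The list of 9 histone genes did not pass as a set (camera adjusted p = 0.813), with 1 higher and 0 lower over all genes and 1 higher and 1 lower adjusted over the list alone. None of 33 respiratory chain genes and none of 43 ribosomal protein genes passed either way in limma, and their camera adjusted p were 0.623 and 0.0527. The ribosomal list (median 0.07) passed as higher in 4 of 12 alternative analyses, with an adjusted p of 7.01e-05 with an intensity trend. None of the genes named here passed with any single array left out. The median and the mean differed in sign for the apoptosis-restraining (0.02 and -0.12), NRF2 (0.02 and -0.04) and NF-κB lists (0.07 and -0.01). They also did for the YAP/TEAD (-0.03 and 0.06), endothelial (0.06 and -0.02) and interferon lists (0.0851 and -0.00617). Camera followed the mean in the apoptosis-restraining, NRF2 and YAP/TEAD lists.

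Marker lists of other cell types were read with human probes, so RNA of the mouse host was seen only through cross-hybridisation. Of 19 fibroblast and pericyte markers, COL5A1 (1.14 ± 0.10) and PDGFRB (1.10 ± 0.19) rose, 2 also when adjusted over the list alone, while the list median was -0.10 (camera adjusted p = 0.623). The interstitial collagen genes COL1A2 (-1.46 ± 0.40, limma adjusted p = 0.077) and COL3A1 (-1.45 ± 0.46, adjusted p = 0.103) did not pass. COL1A2 was dim, with a mean intensity of 63.8 in the controls and 23.2 in the knockdown tumours, the latter below 34.3. The myeloid list of 9 tested genes had a median of -0.20 (camera adjusted p = 0.0632) and passed as lower in 4 of 12 alternative analyses, among them those without control replicate 1 (-0.31, adjusted p = 0.0277) and without knockdown replicate 2 (-0.22, adjusted p = 0.0135), and LAPTM5 fell (-0.53 ± 0.07), alone also when adjusted over the list alone. Of 9 endothelial markers, ENG rose (0.56 ± 0.08) and SOX18 fell (-0.62 ± 0.08), with 1 and 2 adjusted over the list alone (camera adjusted p = 0.947). CD8A fell (-0.57 ± 0.09) among 6 lymphocyte markers, alone also when adjusted over the list alone (camera adjusted p = 0.285). Its mean intensity was 43.4 in the controls and 29.2 in the knockdown tumours, the latter below 34.3, so the fold is at least 1.27 only. The myelin gene PMP22 rose (0.58 ± 0.07) among 5 nerve markers, 2 when adjusted over the list alone (camera adjusted p = 0.201, and 0.0392 without knockdown replicate 1). None of 8 adipocyte markers (camera adjusted p = 0.623), 10 skeletal muscle markers (camera adjusted p = 0.947), 3 red blood cell markers and 4 mammary and skin markers passed, and the last list had 1 higher and 1 lower member when adjusted over the list alone. In fits with 1 array left out, 1 fibroblast or pericyte marker passed without control replicate 1, 2 adipocyte markers passed as higher without knockdown replicate 1, and 0 markers of these lists passed otherwise. The adipocyte genes CIDEA and FABP4 read 173 and 139 on knockdown replicate 2, against 43.6 to 52.9 and 41.6 to 49.4 on the other arrays.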

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

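All 3 results here were chosen after the result was seen, from probe sets outside the comparison of named genes. Of 463 probe sets with no gene symbol that lay above the intensity filter, 17 were higher and 3 lower in the knockdown tumours at a limma adjusted p under 0.05, in data that no gene name covers. Of 391 probe sets assigned to several genes, 14 were higher and 4 lower, and the gene behind each was not resolved. These shares, 4.32% and 4.60%, lie below the 6.29% of the probe sets with 1 symbol that passed in the same fit. The control probe set for Alu repeats, left out of the test with the other array controls, was brighter on both knockdown arrays (23402 and 24081) than on both control arrays (21673 and 22188), a ratio of 1.083 between the group means, while the 18S ribosomal RNA probe sets were dimmer on both. The Alu values were the highest on the knockdown arrays, whose maxima also exceeded those of the controls (22916 and 23075), so at this end of the range the ratio is not read as a change in RNA.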

How the results depend on the processing

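The alternatives were planned before the data were examined, and none was added afterwards. TSPAN12 passed in every fit, with differences of -2.54 to -2.48. Among named genes that passed in the main fit or in the alternative, only ME1 changed direction. It moved to 0.189 (limma adjusted p = 0.763) with the mean of its probe sets, 1 of which gave 1.75. Named genes that passed in neither fit were not checked for direction. Calls numbered 729 higher and 880 lower with an intensity trend, 951 and 1047 at a threshold of 0.1, and 54 and 33 with a 2-fold minimum, the last because the test adds a condition. Leaving out 1 array gave 19 to 33 higher and 12 to 18 lower genes, since 1 residual degree of freedom remains and the lone sample is assumed to vary like the other group. With the replicate number as a block, which also leaves 1, 23 genes were higher and 11 lower, all 34 among the 1002. The numbers share nothing else, since the replicate deviations correlated at -0.01 across genes. The block changed no call of the mitosis, replication, hypoxia, TGF-β or heat shock list, and 4 lists in place of 3 passed as lower. Among 95 named genes that passed, 83 passed with no filter, 94 with a trend, 91 after quantile normalization, 93 after median centring and 19 with the block. Median centring lowered the share of higher calls from 45.9% to 38.5%. Leaving out the lower-expressed genes, 50 percent in all, gave 24 higher and 15 lower genes at least 2-fold apart without overlap, because fewer genes were tested. It also ended the calls of the heat shock list (-0.1542, adjusted p = 0.0516) and the TGF-β list (0.1803, adjusted p = 0.0516), and the cause was not tested. The same setting added calls of the Wnt component (0.117, adjusted p = 0.0392) and ribosomal (0.0661, adjusted p = 0.031) lists as higher and of the epithelial list (-0.186, adjusted p = 0.0136) as lower. Of the lists not called at first, over 12 alternatives, the ribosomal and myeloid lists passed in 4 each, and the Wnt component, epithelial, unfolded protein response and nerve lists in 1 each. Without 1 array the heat shock median ranged from -0.2661 to -0.1095, the call being lost without control replicate 1 (adjusted p = 0.169) and without knockdown replicate 1 (adjusted p = 0.0934), and the TGF-β median from 0.1969 to 0.4223. With an estimated correlation 0 lists were higher and 0 lower, and with fry 0 and 0. The medians do not change with the test: mitosis -0.4604 (adjusted p = 0.802 with an estimated correlation, 0.104 with fry), replication -0.2174 (0.802 and 0.112), hypoxia 0.4774 (0.802 and 0.0648), TGF-β 0.3082 (0.802 and 0.112) and heat shock -0.2036 (0.883 and 0.211). In the simulation a list shifted by -0.46 was also missed with an estimated correlation (adjusted p = 0.109) but found by fry (adjusted p = 0.0231), which did not call the measured mitosis list. The simulated genes were independent. The estimated correlation was 0.636 in the mitosis list, 0.369 in replication, 0.639 in heat shock, 0.151 in TGF-β and -0.0082 in hypoxia. The simulation therefore cannot show why the measured calls were lost, or that a preset correlation of 0.01 holds for such lists. Signal near background limits the genes with a mean intensity under 34.3, which were not tested.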

Other observations

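The gene families below, and all tests here except those of tumour pieces and of a single knockdown array, were chosen after the result was seen. All 6 HLA class I genes tested, which present peptides to CD8 T cells, were higher in the knockdown tumours. HLA-B rose 1.97-fold (0.98 ± 0.08 on the log2 scale, limma adjusted p = 0.012), HLA-C 1.73-fold (0.79 ± 0.08) and HLA-E 1.30-fold (0.37 ± 0.07, adjusted p = 0.0369). All 20 class I probe sets had both knockdown arrays above both controls. The light chain gene B2M (0.17, adjusted p = 0.167) and the peptide transporter gene TAP1 (0.26, adjusted p = 0.1) did not pass, and neither did any of the 7 tested class II genes. Of 119 symbol families with at least 10 tested members, 2 were enriched among higher genes by a one-sided Fisher's exact test with Benjamini-Hochberg adjustment over 238 tests. These were HLA (6 of 13 higher against 0.625 by chance, adjusted p = 0.00367) and the collagens (6 of 18 against 0.866, adjusted p = 0.0162). Fisher's exact test counts genes as independent, and its p-values carry no spread between samples. The 6 HLA genes were each read by a probe set with the suffix _x_at, so they may share signal and count as fewer than 6.

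The collagens that rose were COL5A1 (1.14 ± 0.10), the basement membrane chains COL4A1 (0.73 ± 0.12) and COL4A2 (0.75 ± 0.09), COL18A1, which holds the endostatin sequence (0.82 ± 0.07), the anchoring fibril chain COL7A1 (0.80 ± 0.10) and COL6A2 (0.51 ± 0.07). The chains COL1A2 (-1.46 ± 0.40) and COL3A1 (-1.45 ± 0.46), abundant in fibroblasts, differed the other way and did not pass. The COL1A2 mean in the knockdown tumours, 23.2, lay below the filter level of 34.3. All 12 HLA class I and collagen genes that rose were also higher after quantile normalization and after median centring. Of these 12, HLA-B and COL5A1 passed without control replicate 1, and 0 passed without any other single array. The 18S ribosomal RNA signal, 1.98-fold lower in the knockdown group, moved with both families.

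The lower level of mitosis genes was set against RNA quality, a general loss of tumour RNA and hypoxia of the pieces taken. Knockdown replicate 2 had the highest 3′ to 5′ ratios of ACTB (2.32, against 1.53 to 1.77 on the other arrays) and GAPDH (1.38, against 1.25 to 1.30). Its poly-A spike signal was the lowest (222, against 533 to 820), but spikes are added RNA and do not measure tumour RNA quality. The mitosis median of knockdown replicate 1 against the control mean was also low, at -0.392, with the controls at -0.0791 and 0.0791. This argues against poorer RNA in replicate 2 as the whole cause. The 95% bootstrap interval of -0.499 to -0.359 resampled member genes as if independent, so it carries no spread between samples. None of 10000 random lists of like level had a median as low as the -0.46 of the mitosis list (0%, with 95% of them from -0.0865 to 0.0696). Camera had already placed the list below other genes, so this restates that result and is no further test. RMA removes a loss shared by all genes, so such a loss alone would not set the list apart. A loss that fell more on some genes was not tested. In 2 of 2 groups the replicate with the higher hypoxia median had the lower mitosis median, but the hypoxia medians differed by 0.0416 and -0.0615 only, so a difference in hypoxia between pieces and an effect of the knockdown on cycling cannot be told apart. An effect of TSPAN12 on proliferation therefore stays a hypothesis, and neither the lower 18S signal of both knockdown arrays nor the CIDEA and FABP4 signal of knockdown replicate 2 (173 and 139) was weighed.

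The rise of TAGLN and other TGF-β response genes, and of the smooth muscle actin gene ACTG2, may reflect host stroma or a change in the tumour cells. Against the control mean, the TGF-β list median was 0.361 in knockdown replicate 1 and 0.227 in replicate 2 (95% bootstrap intervals over genes within 0.0148 to 0.583). The controls lay at 0.0915 and -0.0915. This argues against a single knockdown array as the whole source, though knockdown replicate 2 stood close to control replicate 1. A control array as part of the source was not tested, and without control replicate 2 the median was 0.20. The fibroblast and pericyte list, of which 1 of 19 genes stands in another list, had a median of -0.102 (95% bootstrap interval over genes -0.24 to 0.0809), below the 0.427 that is 50 percent of the median of the TGF-β members that passed. Its brightest members, FBN1 (968 in controls and 982 in knockdown tumours) and COL6A3 (386 and 436), did not pass, while COL5A1 (166 and 365) and PDGFRB, a pericyte gene, rose. Human probes read mouse RNA only through cross-hybridisation and a high level in the tumour cells would hide a small share of host RNA, so more host fibroblasts and pericytes and a change in the tumour cells cannot be told apart.

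The HLA class I rise could come from interferon signalling or from probes that read several class I genes. The interferon list median of 0.0851 (95% bootstrap interval over genes -0.0216 to 0.182) lay below 0.248, which is 50 percent of the class I median. That argues against a rise of that size across the whole list. Its members went both ways: MX1, IFI44 and GBP1 fell and MX2 rose. Of 38 tested, 14 had both knockdown arrays above both controls and 7 had both below. An interferon response of part of the list therefore stays open. The HLA-E probe set designed for 1 gene differed by 0.305 (unadjusted 95% t interval 0.103 to 0.507) and did not pass (limma adjusted p = 0.0811 over probe sets), but the interval lies above 0, which argues against signal of a near copy as the whole difference in HLA-E. For the other 5 class I genes, 0 had such a probe set above the filter, so a rise of each gene and shared signal cannot be told apart. The class I rise stays a hypothesis at the level of the family.

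With 4 arrays only 3 splits into pairs exist, too few for a share under 0.05. The split by label gave 1002 genes in limma, or 2939 at an unadjusted p under 0.05, and each of the other 2 splits gave 0, with at most 72 at an unadjusted p under 0.05. In each of these 2, both groups held 1 control and 1 knockdown array, so the knockdown difference entered the residual spread and held the counts down, and they say nothing about chance.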
